A study of Mus musculus with 16 samples.

How the data were processed

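Gene expression was measured in liver RNA from 16 mouse offspring, 1 two-colour array for each animal. The groups, taken from the sample labels, were female control (3 arrays), female UV-Titan (5), male control (4) and male UV-Titan (4). Per the labels' protocols, 200 ng of total RNA from random sections of each liver was amplified, labelled and hybridised to Agilent mouse 4 x 44 arrays together with a universal mouse reference RNA. The arrays lay on 5 slides scanned on 4 days.

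Two-channel spot intensity values were deposited for each array. The mean spot intensity and local background intensity of each channel were taken as scanned, with no correction, per the file headers. The processed intensity values had been background-subtracted with spatial detrending, multiplicatively detrended and dye-normalised by linear and lowess fits in Agilent Feature Extraction 9.5.3.1 (version per the labels), per the file headers. The authors also deposited a table of log2 ratios, whose normalisation is not stated. Its scale (log2) and direction (red over green) were found by setting each column against the scanner signals of the same array (r 0.946 to 0.995, slope 0.894 to 0.989), and its column medians lay between -0.045 and -0.0375. The label fields name Cy3 for liver and the labelling protocol names Cy5. The rule for settling this was that the channel in which hepatocyte markers were brighter on all 16 arrays and in which Y-linked genes separated the sexes holds liver, and both checks pointed to red.

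Each array had 45018 spots, 43379 of them not controls, for 41174 distinct probes. Between 90 and 135 spots per array had outlier marks and were left out, and 0 spots were saturated. Both channels were background-corrected with normexp (offset 50) and normalised by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots of a probe were averaged. A gene was tested where a probe was well above background in the liver channel on at least 3 arrays, and the probe with the highest mean liver signal stood for the gene. This gave 19363 genes, of which 6112 had several tested probes and 1 further gene was left out because a group had no value. Accessions without versions were matched to a symbol table of assembly GRCm38.p6, used for names only, for 12357 genes, and 7006 kept the name in the array file, which can be old, so Kdm5c and Jarid1c stand for the same gene. Positions are those of the array files in build mm7. Pearson's r between arrays of a group, across genes, which are not independent replicates, was 0.969 to 0.981 in female controls, 0.982 to 0.991 in female UV-Titan, 0.973 to 0.983 in male controls and 0.979 to 0.989 in male UV-Titan.

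One limma model with a mean for each of the 4 groups was fitted to all 16 arrays, so that the groups shared an estimate of the spread. Its contrasts were UV-Titan against control in females, in males and averaged over both, the difference between the female and the male effect, and male against female. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and every adjusted p for a gene comes from limma. Where a gene was not well above background on any array of a group, or on most of them as for Ddx3y, the fold is a lower bound. It sets the mean of the bright group against, per array of the dim group, the higher of the probe's own signal and the lowest signal well above background, on liver-channel values after loess and Aquantile, which stay open to dye bias because no dyes were swapped.

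There were 37 gene lists for pathways, cell types and other organs, and 36 had at least 5 measured genes. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way without setting them against other genes. The mean of each list per array was tested by exact two-sided permutation of the exposure labels, within sex where both sexes entered. The permutations numbered 56 in females, 70 in males and 3920 over both, and the smallest p they can give is 0.018, 0.029 and 0.00026. Genes were also adjusted over each list alone. That adjustment does not correct for the number of lists or comparisons, so some genes can pass it by chance.

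The comparisons, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except the alternatives marked as added. The rule named, for each comparison, the 12 genes in each direction with the largest change past the threshold, filled up to 8 by the smallest unadjusted p among genes well above background on every array of a group. It further named up to 4 members with the smallest p of each list described, Xist, Ddx3y, Kdm5d, Eif2s3y and Uty, and a panel of Afp, Alb, Hbb-b1, Cyp26a1, Mt1, Mt2, Saa1, Saa2 and Cdkn1a, of which Hbb-b1 was not among the genes tested. The text gives a selection of these for lists called in only some settings. Some genes that the rule names are not reported here. The alternatives covered background correction, normalisation, the liver channel alone (quantile-normalised between arrays), the filter on dim probes, outlier spots, the choice of probe, slide and scan day as blocks, the samples in the fit, the variance model, array weights, the authors' log2 table, the threshold, and each array left out in turn. Added after seeing the data were fits without the 2 arrays with pancreas transcripts, without the array with muscle transcripts, without slide 5, and the liver channel alone with slide as a block.

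The gene and list tests were tested on simulated data with the real spread of each gene (19335 genes). Noise was drawn independently for each gene. With no correlation between genes, the simulation cannot tell how often camera calls unchanged lists on the real arrays. In the female comparison 62.7% of genes changed by 0.5 log2, 97% of those changed by 1 and 100% of those changed by 2 were called, and 0.042% of unchanged genes. In the male comparison the shares were 73.1%, 92.5%, 100% and 0.063%. The median estimates lay below the planted sizes, at 0.422, 0.821 and 1.73 log2 in females and 0.397, 0.803 and 1.82 in males. The shares called hold for these planted changes and independent noise, and do not give the power on the real arrays. In females a list shifted by 0.3 log2 was called (camera adjusted p = 4.45e-09) and 0 other lists were called by camera and 0 by fry. In males, with no list shifted, 0 other lists were called by camera and 1 by fry.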

Results

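Livers of mouse offspring were profiled to ask whether inhalation of UV-Titan, a surface-coated nano-sized titanium dioxide, by the dam during pregnancy changed gene expression in the liver of the offspring. Time-mated C57BL/6BomTac mice had breathed filtered air or about 42 mg/m3 UV-Titan for 1 hour a day on gestation days 8 to 18. The 16 offspring fell into 4 groups: female control (3 animals), female UV-Titan (5), male control (4) and male UV-Titan (4), with 1 array for each animal. The labels do not say whether a liver came from a newborn on postnatal day 2 or from a weanling on postnatal days 23 to 24, nor which animals shared a litter. In the liver channel 57.7% to 67.1% of spots per array were well above background, and in the reference channel 62.7% to 69.8%. The number of arrays limits the precision of every comparison.

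The label fields and the labelling protocol gave opposite dyes, and the signals settled which channel held liver. Markers of hepatocytes, the main cell of the liver, had a median log2 ratio of red over green between 5.55 and 6.78 on the 16 arrays, so red was read as liver and green as the common reference. Xist, the RNA that silences the second X chromosome of females, had a log2 ratio of 1.88 ± 0.13 (SD, n = 8) in females and -5.69 ± 0.40 (SD, n = 8) in males. Ddx3y, an RNA helicase gene on the Y chromosome, had a log2 ratio of 1.82 ± 0.14 (SD, n = 8) in males and -1.93 ± 0.25 (SD, n = 8) in females. In the green channel the same genes differed between the sexes by 0.10 and 0.03 log2. The sex label matched Xist and Ddx3y on all 16 arrays.

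In female offspring, transcripts of platelets and of their precursor cell, the megakaryocyte, were higher after maternal UV-Titan. All 12 measured genes of the megakaryocyte and platelet list had a higher mean on the 5 UV-Titan arrays than on the 3 control arrays, and the list mean rose by 0.53 ± 0.10 log2 (SE). Gp1bb rose by 0.58 ± 0.09, Gp5 by 0.60 ± 0.12 and Gp9 by 0.49 ± 0.09 log2 when adjusted over the list alone. These encode parts of the platelet receptor for von Willebrand factor. Treml1, a receptor stored in platelet granules, rose by 0.55 ± 0.10 log2 on the same basis. Adjusted over the list alone 12 of 12 genes passed, against 0 over all genes tested. The list passed limma's camera (adjusted p = 2.04e-25), also with the gene correlation estimated from the data (adjusted p = 0.0453 with an estimated correlation), and limma's fry (adjusted p = 0.00382). Every female UV-Titan array lay above every female control array, which in an exact permutation test gives the smallest two-sided p that 56 relabellings allow, 0.0179, or 0.165 after Benjamini-Hochberg over 37 lists. Female control replicates 35 and 25 had the lowest array weights of the 16 arrays (0.395 and 0.571), and replicate 35 the lowest share of liver-channel spots well above background. The list was 0.51 ± 0.09 log2 with array weights, 0.57 without replicate 35 and 0.47 without replicate 25. The value was 0.49 ± 0.08 log2 with slide as a block, and 0.45, 0.56 and 0.52 log2 within the 3 slides that held both female groups.

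**Figure D1:**
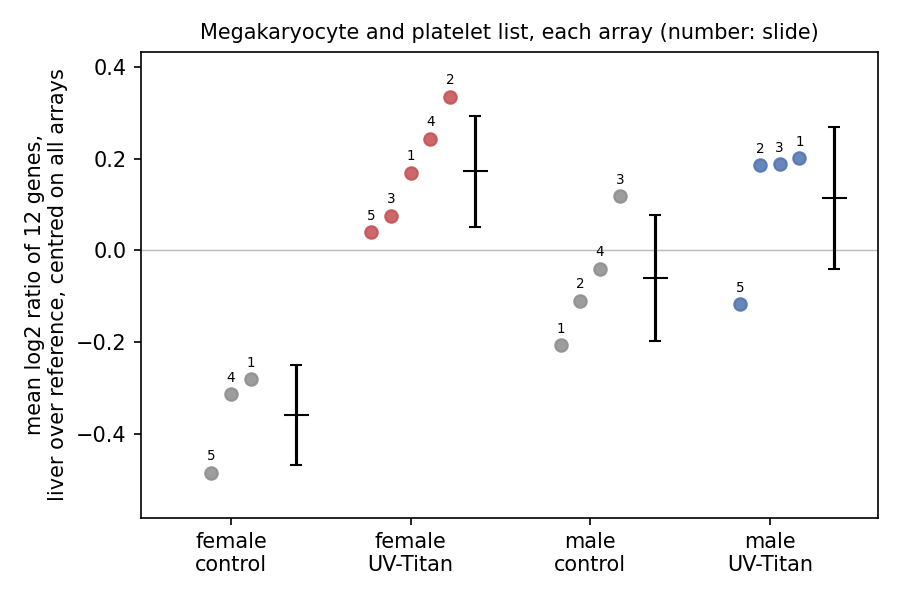
Mean log2 ratio (liver over reference) of the 12 genes of the megakaryocyte and platelet list on each array, centred on all 16 arrays, by group; the number at each point is the slide, and the bars are the group mean ± SD. The 5 female UV-Titan arrays lie between 0.04 and 0.34, and the 3 female control arrays between -0.48 and -0.28.

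**Figure D2:**
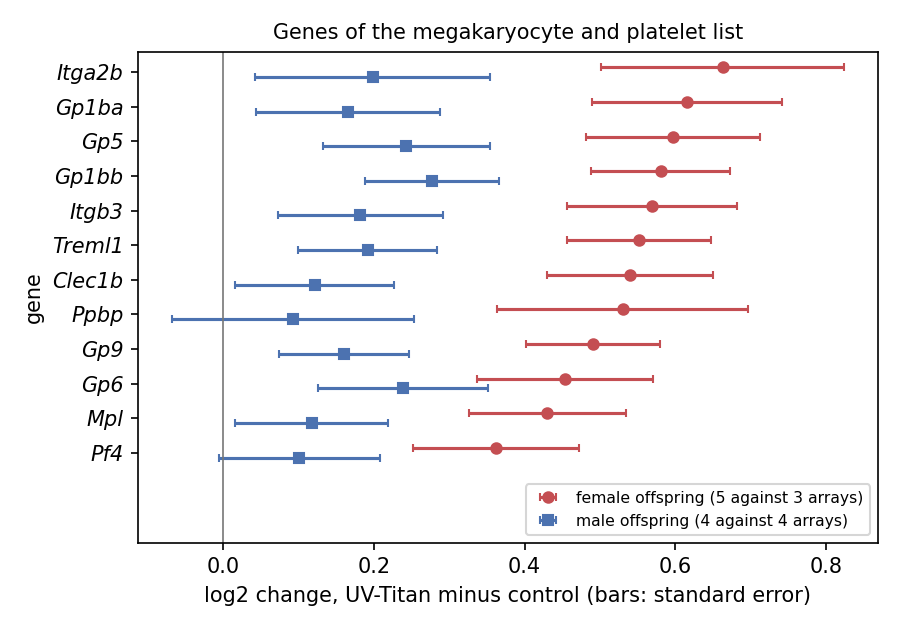
Log2 change between UV-Titan and control for each of the 12 genes of the megakaryocyte and platelet list in female (5 against 3 arrays) and male (4 against 4 arrays) offspring; the bars are the standard error. All 12 values are above 0 in both sexes, from 0.36 to 0.66 in females and from 0.09 to 0.28 in males.

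Granulocyte transcripts were higher in the same animals. All 19 measured genes of the granulocyte list had higher means with UV-Titan, the list mean rose by 0.45 ± 0.13 log2 (SE), and 12 genes passed when adjusted over the list alone. Mmp8, a collagenase stored in neutrophil granules, rose by 0.63 ± 0.13, Chil3, a chitinase-like protein of myeloid cells, by 0.74 ± 0.22, Retnlg, a resistin-like protein, by 0.57 ± 0.16, and Fcnb, a ficolin of myeloid cells, by 0.49 ± 0.13 log2 on that basis. The list passed camera (adjusted p = 1.16e-16) and fry (adjusted p = 0.0421), not camera with the correlation estimated (adjusted p = 0.12 with an estimated correlation). The macrophage and Kupffer cell list also passed camera at 0.20 ± 0.07 log2 (SE, adjusted p = 2.63e-05; adjusted p = 0.296 with an estimated correlation). In the liver channel alone, quantile-normalised between arrays, the granulocyte list was 0.32 ± 0.12 log2 and still called, and the macrophage list 0.04 ± 0.06 and not called (adjusted p = 0.674). Of the 21 genes of the macrophage list 19 had higher means by ratio, with Lyz1 and Lyz2, lysozymes of phagocytes, at 0.38 ± 0.11 and 0.38 ± 0.15 log2, not past the threshold. Lyz2 was 0.25 without female control replicate 25 and 0.60 without replicate 35.

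Liver-cell genes were also higher in females by ratio, and by less in the liver channel itself. All 21 measured genes of the hepatocyte list had higher ratios, with a list mean of 0.56 ± 0.25 log2 (SE; camera adjusted p = 3.95e-13; adjusted p = 0.296 with an estimated correlation). The size in the liver channel depended on the normalisation. With each array centred on its median the list mean was 0.19 ± 0.10 log2 in the liver channel and -0.42 ± 0.23 in the reference channel. After quantile normalisation between arrays, as for the other lists and genes given for the liver channel alone, it was 0.04 ± 0.05 in the liver channel, not called (adjusted p = 0.412), and -0.42 ± 0.24 in the reference channel. Ttr and Tat, the thyroid hormone carrier transthyretin and tyrosine aminotransferase, passed when adjusted over the list alone at 0.49 ± 0.15 and 0.44 ± 0.13 log2. Ttr was -0.08 log2 in the liver channel alone and Tat 0.54. Alb, the serum albumin gene, had 0.87 ± 0.34 log2 by ratio and -0.07 log2 in the liver channel. Afp, the fetal counterpart of albumin, had 0.79 ± 0.44 log2 by ratio and -0.00054 log2 in the liver channel. Neither passed.

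Acute phase proteins, made by hepatocytes in inflammation, passed camera at 0.32 ± 0.11 log2 (SE; adjusted p = 3.06e-06; adjusted p = 0.296 with an estimated correlation), with 19 of 23 genes higher. Lcn2 had 0.43 ± 0.13, Lbp 0.33 ± 0.11, Hpx 0.52 ± 0.17 and Itih4 0.31 ± 0.12 log2, none past the threshold. Saa1 and Saa2, the most inducible acute phase genes, had -0.02 ± 0.12 and -0.07 ± 0.09 log2. Glucose and amino acid metabolism passed camera at 0.31 ± 0.14, erythroid markers at 0.18 ± 0.11 and fetal and imprinted liver genes at 0.22 ± 0.11 log2 (adjusted p = 2.05e-07, 4.75e-05 and 0.00869; adjusted p = 0.296, 0.49 and 0.49 with an estimated correlation). None of these 4 lists was called in the liver channel alone, with acute phase proteins at 0.09 ± 0.07, glucose and amino acid metabolism at 0.07 ± 0.08, erythroid markers at -0.02 ± 0.21 and fetal and imprinted liver genes at 0.04 ± 0.05 log2 (adjusted p = 0.0567, 0.579, 0.931 and 0.632). Hba-a1, an alpha globin gene, had 0.57 ± 0.23 by ratio and 0.02 log2 in the liver channel, Ermap 0.41 ± 0.14 and 0.06, and Gata1, the erythroid transcription factor, 0.21 ± 0.07 and 0.04. Tspan33 had 0.26 ± 0.11 by ratio and -0.21 in the liver channel. None of these 4 genes passed.

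Of 7 other lists called in females, 4 lost the call without at least 1 array. Endothelial markers passed at 0.21 ± 0.09 log2, with Stab1 and Clec4g of the liver sinusoid at 0.38 ± 0.11 and 0.43 ± 0.15, Egfl7 at 0.36 ± 0.13 and Kdr, a receptor for vascular growth factor, at 0.42 ± 0.18, none past the threshold. Without female control replicate 25 the endothelial list was 0.13, xenobiotic metabolism went from 0.23 ± 0.10 to 0.14 and bile acid synthesis and transport from 0.27 ± 0.10 to 0.14 log2, still called. The call ended for fatty acid oxidation and PPAR-alpha targets (0.18 ± 0.12, and 0.057 without female control replicate 25 or 0.12 without female UV-Titan replicate 8) and for cholesterol synthesis (0.14 ± 0.13, and 0.050 without female control replicate 40, 0.13 without female UV-Titan replicate 2 or 0.13 without replicate 16). It also ended for adult liver genes higher in females (0.19 ± 0.11, and 0.063 without female control replicate 25, 0.17 without replicate 40 or 0.14 without female UV-Titan replicate 8). Without female control replicate 35 that list was 0.32 and still called. Cell proliferation was the list lower with UV-Titan, at -0.09 ± 0.13 log2 (-0.16 without female control replicate 35), and its call ended at -0.019 without female UV-Titan replicate 8 and at -0.03 without female control replicate 40. Camera's adjusted p for these 7 lists was between 1.11e-05 and 0.0194, and between 0.296 and 0.686 with an estimated correlation. Camera called 15 of 36 lists in females, 14 higher and 1 lower, fry called 2, and camera with an estimated correlation called 1, the megakaryocyte and platelet list. In the liver channel alone camera called 7 lists. Endothelial markers (0.08 ± 0.08), cholesterol synthesis (0.10 ± 0.13) and cell proliferation (-0.14 ± 0.14) kept the call, while xenobiotic metabolism (0.01 ± 0.06), bile acid synthesis (0.06 ± 0.05), fatty acid oxidation (-0.03 ± 0.10) and adult liver genes higher in females (-0.01 ± 0.08 log2) lost it.

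Gene by gene, limma called 0 of 19363 genes in females at an adjusted p below 0.05, with 1295 genes below an unadjusted p of 0.05 (1047 higher, 248 lower; 968 expected by chance). The smallest adjusted p was 0.084, that of Gp1bb, Treml1, Vwf, Itgb2l and Tnfsf14. Vwf, the adhesive protein of platelets and endothelium, had 0.47 ± 0.08, Itgb2l, an integrin chain, 0.53 ± 0.09, Tnfsf14, a TNF family cytokine, 0.56 ± 0.09, and Ltb4r1, the leukotriene B4 receptor of leukocytes, 0.56 ± 0.11 log2. For each of these 4 all 5 UV-Titan arrays lay above all 3 control arrays. The genes with the smallest p among those lower were Cst6 at -0.41 ± 0.10, Lrp8, a receptor for reelin and apolipoprotein E, at -0.39 ± 0.10, Sh3bp4 at -0.35 ± 0.10, Tmem145 at -0.30 ± 0.08, Trappc13 at -0.28 ± 0.08, Zfp936 at -0.25 ± 0.08, Glt28d1 at -0.24 ± 0.07 and Zfp958 at -0.24 ± 0.06 log2, with adjusted p from 0.432 to 0.631. Sh3bp4 was -0.52 without female control replicate 40 and -0.22 without replicate 35. Ltb4r1 passed with slide as a block (adjusted p = 0.0315) and with scan day as a block (adjusted p = 0.0134). With array weights the genes that passed in limma included Gp1bb, Gp9, Treml1 and Itgb2l (each adjusted p = 0.0238).

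**Figure D3:**
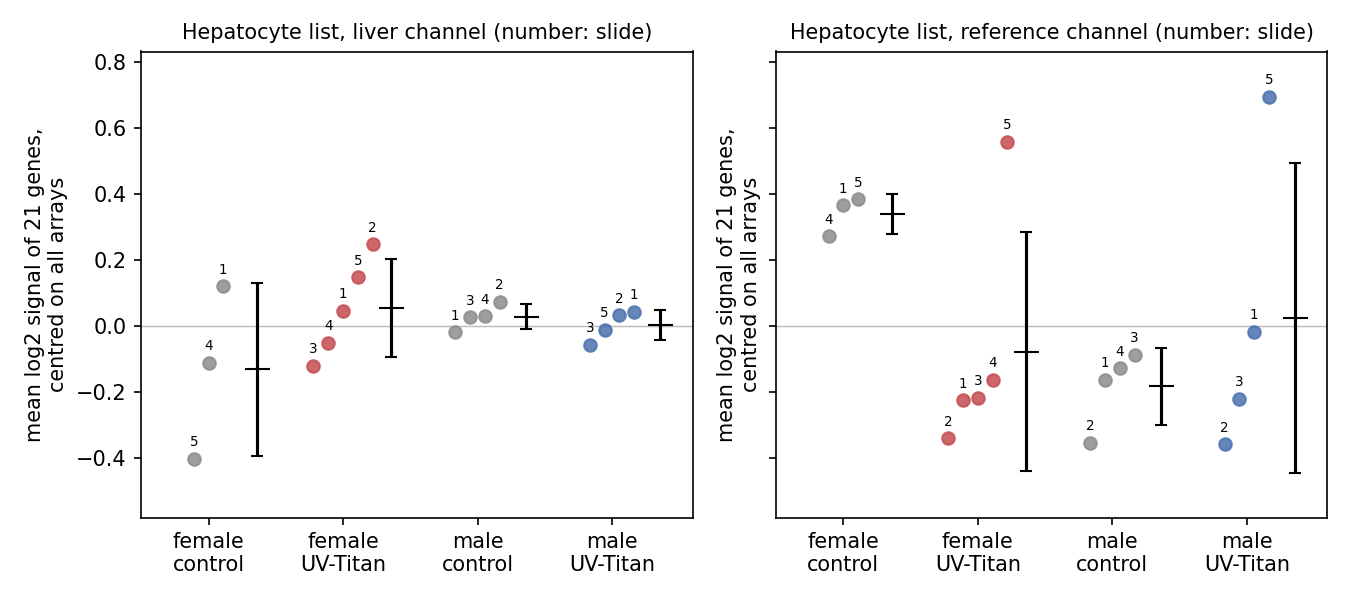
Mean log2 signal of the 21 genes of the hepatocyte list on each array, in the liver channel (left) and the reference channel (right), each array centred on its median and each gene on all 16 arrays; the number at each point is the slide, and the bars are the group mean ± SD. Between female UV-Titan and female control the mean differed by 0.19 ± 0.10 (SE) in the liver channel and by -0.42 ± 0.23 in the reference channel.

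In male offspring the megakaryocyte and platelet list showed the same sign at a smaller size. All 12 genes had higher means on the 4 UV-Titan arrays than on the 4 control arrays, and the list mean was 0.17 ± 0.09 log2 (SE; camera adjusted p = 9.94e-05; adjusted p = 0.748 with an estimated correlation), with 0 genes passing when adjusted over the list alone. Gp1bb had 0.28 ± 0.09, Gp5 0.24 ± 0.11, Treml1 0.19 ± 0.09 and Gp6, the platelet collagen receptor, 0.24 ± 0.11 log2. Within the 3 slides that held both male groups the list differed by 0.41, 0.30 and 0.07 log2. The exact permutation p over 70 relabellings was 0.171, where 0.029 is the smallest possible. Fatty acid oxidation and PPAR-alpha targets were lower, with 26 of 29 genes below 0 and a list mean of -0.21 ± 0.12 log2 (SE; camera adjusted p = 1.1e-09; adjusted p = 0.748 with an estimated correlation). Acot1 and Acot2, acyl-CoA thioesterases, were lower by 1.14 ± 0.33 and 0.59 ± 0.17 log2. They passed only when adjusted over the list alone, which leaves the number of lists uncorrected. Acadm and Ehhadh, enzymes of beta oxidation, had -0.29 ± 0.10 and -0.38 ± 0.16 log2, not past. The respiratory chain list passed camera at -0.09 ± 0.07 and the oxidative stress and NRF2 list at -0.07 ± 0.05 log2 (adjusted p = 0.000234 and 0.00213; both 0.748 with an estimated correlation). The respiratory chain list was -0.05 ± 0.04 log2 in the liver channel alone and lost the call (adjusted p = 0.0684). Etfa, the electron transfer flavoprotein, was the respiratory chain gene past when adjusted over the list alone, at -0.39 ± 0.10 by ratio and 0.01 log2 in the liver channel alone. Uqcrc2, Atp5o and Cox7c had -0.16 ± 0.09, -0.10 ± 0.08 and -0.24 ± 0.22 log2, and without male control replicate 33 Atp5o was -0.06 and Cox7c -0.12.

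Transcripts of other organs stood out on 3 male arrays. Digestive enzymes of the exocrine pancreas were high in male control replicates 31 and 33, where the pancreas list scored 2.44 and 1.43 log2 above the mean of all arrays, against -0.42 to -0.16 on the other 14. The list mean between male UV-Titan and male control was -1.05 ± 0.48 log2 (SE; camera adjusted p = 5.97e-15; adjusted p = 0.748 with an estimated correlation), with 11 of 17 genes past when adjusted over the list alone. It was -0.50 without replicate 31 and 0.076 without both. Zg16 had -0.92 ± 0.30, Clps, the pancreatic colipase, -1.68 ± 0.61 and Sycn -1.01 ± 0.38 log2, and -0.50, -0.98 and -0.58 without replicate 31. Without those 2 arrays the fatty acid oxidation list was -0.08 log2, still called, and the oxidative stress list -0.03, no longer called. Skeletal muscle genes were high in male UV-Titan replicate 5, with a muscle list score of 1.88 against 0.34 on the next array. The muscle list mean was 0.57 ± 0.39 log2 (camera adjusted p = 0.00213; adjusted p = 0.748 with an estimated correlation) and 0.047 without replicate 5. Tnni2 had 0.63 ± 0.32, Tnnt3 0.66 ± 0.38, Myl1 1.14 ± 0.68 and Myh8 1.09 ± 0.65 log2, none past the threshold, and 0.08 to 0.15 without replicate 5.

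**Figure D4:**
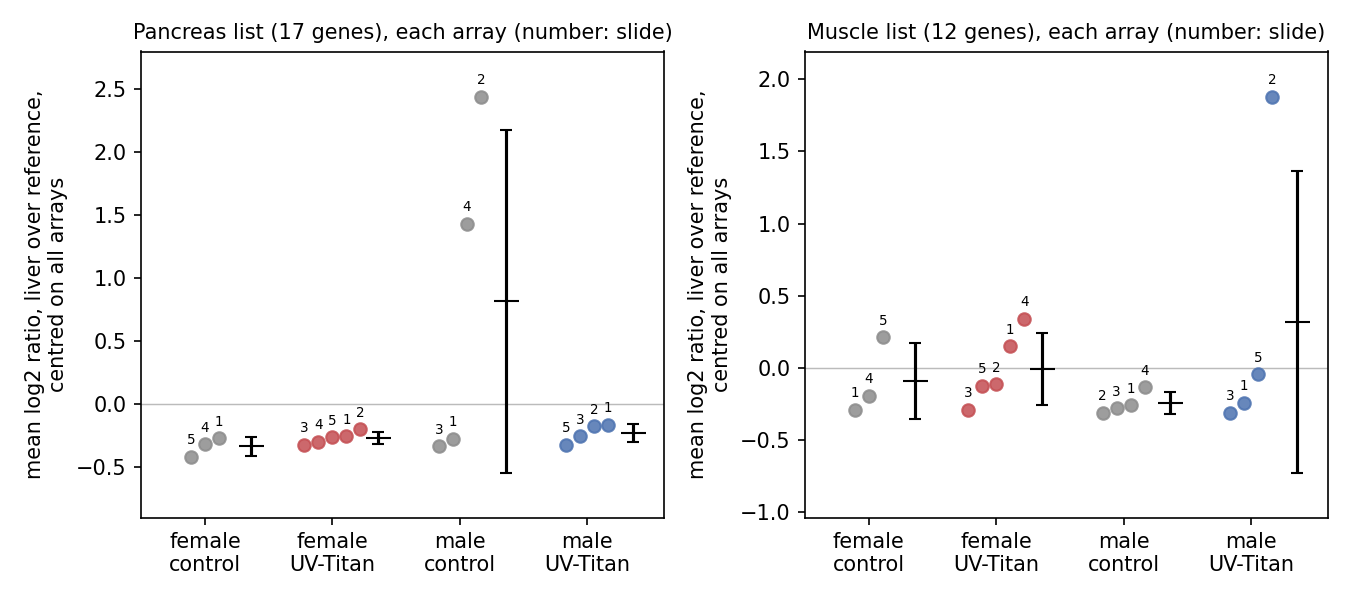
Mean log2 ratio (liver over reference) of the pancreas list (17 genes, left) and the muscle list (12 genes, right) on each array, centred on all 16 arrays, by group; the number at each point is the slide, and the bars are the group mean ± SD. Male control replicates 31 (slide 2) and 33 (slide 4) reach 2.44 and 1.43 on the pancreas list, and male UV-Titan replicate 5 (slide 2) reaches 1.88 on the muscle list.

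The other 5 lists called in males each lost the call without at least 1 array. Hepatocyte markers had -0.19 ± 0.24 and glucose and amino acid metabolism -0.12 ± 0.13 log2, and both turned to 0.050 and 0.0024 without male UV-Titan replicate 17. Hepatocyte markers also lost the call without male control replicate 31, at -0.10, and glucose and amino acid metabolism without male control replicate 33, at -0.08. Without male UV-Titan replicate 5 these lists were -0.34 and -0.21, still called. In the liver channel alone the hepatocyte list had a small value of the opposite sign. Xenobiotic metabolism had -0.11 ± 0.09, and -0.04 without male UV-Titan replicate 17. Stellate cell and matrix genes had 0.17 ± 0.16 and lost the call without male UV-Titan replicates 5 (0.065) or 3 (0.094) and without male control replicates 41 (0.099) or 43 (0.12). Without male control replicate 31 or male UV-Titan replicate 17 that list was 0.26, still called. Fatty acid and triglyceride synthesis had -0.08 ± 0.08 and lost the call at -0.02 without male control replicate 31, at -0.05 without replicate 43, and at -0.08 to -0.07 without male UV-Titan replicates 5, 3 or 17 or female control replicate 35. Without male control replicate 41 it was -0.16, still called. Camera called 11 of 36 lists in males, 3 higher and 8 lower, fry called 0, and camera with an estimated correlation called 0. Camera's adjusted p for these 5 lists lay between 0.000234 and 0.0407, and was 0.748 for each with an estimated correlation.

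Limma called 0 of 19363 genes in males, with 957 below an unadjusted p of 0.05 (605 higher, 352 lower; 968 expected by chance), and the smallest adjusted p was 0.952. Cnn2, an actin-binding calponin, had 0.31 ± 0.06, Apol9b 0.41 ± 0.09, Ugt3a2, a glycosyltransferase, 0.76 ± 0.18, Neil1, a DNA glycosylase, 0.30 ± 0.07, Pdzk1ip1 0.35 ± 0.09, Odz4 0.44 ± 0.11 and Nat8l 0.42 ± 0.11 log2. Gpt2, a mitochondrial alanine aminotransferase, had -0.45 ± 0.09, Slc25a32, a mitochondrial folate carrier, -0.50 ± 0.12, Raet1a -0.47 ± 0.12, Myc -0.38 ± 0.09, Erbin -0.32 ± 0.09, Crls1, the cardiolipin synthase, -0.32 ± 0.09, and Pdp1, which activates pyruvate dehydrogenase, -0.24 ± 0.06 log2. None of these genes passed over all genes, and Neil1 and Myc passed when adjusted over the list alone (DNA repair and immediate early genes, lists that camera did not call).

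Over both sexes, with the exposure effect averaged over females and males, the megakaryocyte and platelet list and the granulocyte list were higher with UV-Titan. The megakaryocyte and platelet list rose by 0.35 ± 0.07 log2 (SE; camera adjusted p = 2.35e-22; fry adjusted p = 0.00553; adjusted p = 0.0725 with an estimated correlation). Its 12 genes passed when adjusted over the list alone, and the list was higher with UV-Titan in 6 of 6 within-slide pairs, by 0.07 to 0.56 log2. An exact permutation test within sex (3920 relabellings) gave p = 0.00179, or 0.0661 after Benjamini-Hochberg over 37 lists. The granulocyte list rose by 0.26 ± 0.09 log2 (camera adjusted p = 1.45e-11; adjusted p = 0.336 with an estimated correlation), with 8 of 19 genes past when adjusted over the list alone and 6 of 6 pairs higher, by 0.13 to 0.55 log2. Mmp8 rose by 0.49 ± 0.09, Itgam, the integrin of myeloid cells, by 0.33 ± 0.08, Fcnb by 0.35 ± 0.09 and Mmp9, the neutrophil gelatinase, by 0.24 ± 0.06 log2 on that basis. In males alone the granulocyte list was not called, with a mean score of 0.085 with UV-Titan and 0.0207 in controls. For both lists the pairs leave out female UV-Titan replicates 8 and 21, male control replicate 33 and male UV-Titan replicate 17. Their slides held no array of the same sex from the other exposure group. Male UV-Titan replicate 17 had the lowest scores of its group, at -0.229 for granulocytes and -0.117 for megakaryocytes. Erythroid markers at 0.14 ± 0.07, endothelial markers at 0.13 ± 0.06, macrophage markers at 0.12 ± 0.05 and acute phase proteins at 0.14 ± 0.08 log2 passed camera with every array left out in turn (adjusted p = 6.76e-05, 0.000293, 0.00161 and 0.00471; each 0.743 with an estimated correlation). In the liver channel alone macrophage markers (0.04 ± 0.05) and acute phase proteins (0.05 ± 0.05 log2) lost the call. None of the erythroid, endothelial, macrophage and acute phase lists was called in males alone. There the acute phase score was lower with UV-Titan (0.00559 against 0.0376 in controls), and the other lists were higher.

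Of the remaining 5 lists called over both sexes, 4 lost the call without at least 1 array. The pancreas list had -0.49 ± 0.35 log2, -0.22 without male control replicate 31, still called, and 0.072 without replicates 31 and 33. Muscle markers had 0.33 ± 0.28 log2, and the call ended at 0.065 without male UV-Titan replicate 5 and at 0.28 to 0.32 without female UV-Titan replicates 2 or 10, female control replicates 35 or 40, or male control replicates 31 or 43. Hepatocyte markers had 0.18 ± 0.17, and the call ended at 0.11 without male UV-Titan replicate 5 and at 0.14 without female control replicate 25. Without male UV-Titan replicate 17 the hepatocyte list was 0.30, still called. Bile acid synthesis had 0.13 ± 0.07, and the call ended at 0.071 without female control replicate 25 and at 0.11 and 0.12 without male UV-Titan replicates 5 and 3. The respiratory chain had -0.05 ± 0.05, and the call ended at 0.00079 without female control replicate 35 and at -0.03 without female UV-Titan replicate 21. Without female control replicate 25 the respiratory chain was -0.09, still called. Camera called 11 of 36 lists over both sexes, fry called 1, and camera with an estimated correlation called 0. Limma called 0 of 19363 genes, with 1365 below an unadjusted p of 0.05 (1066 higher, 299 lower). The 10 genes below an adjusted p of 0.10, each at 0.0916, included Gp1bb at 0.43 ± 0.06, Treml1 at 0.37 ± 0.07, Tnfsf14 at 0.37 ± 0.06, Itgb2l at 0.37 ± 0.06, Slc2a3, a glucose transporter of blood cells, at 0.34 ± 0.06, Ly6c at 0.33 ± 0.06, Vwf at 0.31 ± 0.06, Cnn2 at 0.25 ± 0.05 and Mmp8 at 0.49 ± 0.09 log2. Among genes with lower values Raet1a, a stress-induced ligand of a natural killer cell receptor, had -0.41 ± 0.09, Acot2 -0.43 ± 0.12, Gpt2 -0.24 ± 0.06, Mdfic -0.22 ± 0.06, Glt28d1 -0.21 ± 0.05, Tmem145 -0.21 ± 0.06, Pdp1 -0.18 ± 0.04 and Zfp958 -0.16 ± 0.04 log2, with adjusted p from 0.177 to 0.403. With scan day as a block 10 genes passed, with slide as a random block 11 and with slide as a fixed block 1.

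Whether the exposure effect differed between the sexes was tested as female minus male. The megakaryocyte and platelet list differed by 0.36 ± 0.13 log2 (SE; camera adjusted p = 3.18e-10; adjusted p = 0.3 with an estimated correlation), and all 12 genes had the higher effect in females. The hepatocyte list differed by 0.74 ± 0.34 log2 by ratio (camera adjusted p = 1.07e-14; adjusted p = 0.3 with an estimated correlation) and by 0.03 ± 0.07 in the liver channel alone. Fabp1, the liver fatty acid binding protein, differed by 1.36 ± 0.56 by ratio and 0.04 in the liver channel, and Trf, transferrin, by 1.17 ± 0.48 and 0.0036, neither past. Camera called 20 of 36 lists in this comparison and 0 with an estimated correlation. Limma called 0 of 19363 genes, with 823 below an unadjusted p of 0.05 and a smallest adjusted p of 0.98. Tat differed by 0.83 ± 0.18, Il1r1, the interleukin 1 receptor, by 0.68 ± 0.19, Atf5 by 0.56 ± 0.15, Cth by 0.54 ± 0.15, Atf6 by 0.50 ± 0.14, Erbin by 0.47 ± 0.13, Ldhal6b by 0.39 ± 0.10 and Ptpru by 0.37 ± 0.11 log2. Lrp8 differed by -0.65 ± 0.14, Irf4 by -0.62 ± 0.17, Tjp3 by -0.52 ± 0.13, Mzb1 by -0.42 ± 0.13, Traf3ip2 by -0.41 ± 0.12, S1pr2 by -0.36 ± 0.11, Ift22 by -0.35 ± 0.10 and Plekhb2 by -0.27 ± 0.08 log2. None passed over all genes, and Tat passed when adjusted over the hepatocyte list alone and over the glucose list alone.

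Male against female offspring, over both exposures, served as a check of the labels and the fit. Limma called 9 of 19363 genes, 4 higher and 5 lower in males (8 arrays each). Eif2s3y, a translation initiation factor gene on the Y chromosome, was at least 22.9-fold higher in males and was not well above background on any female array (adjusted p = 1.49e-14). Ddx3y was at least 14.1-fold higher in males and well above background on 2 of 8 female arrays (adjusted p = 3.53e-14). Kdm5d, a Y-linked histone demethylase, was at least 1.76-fold higher (adjusted p = 2.19e-07). AK053080, placed on unassembled Y sequence in build mm7, was at least 1.61-fold higher (adjusted p = 6.59e-06). Xist fell by 7.57 ± 0.14 log2 (adjusted p = 9.57e-16), Eif2s3x by 0.45 ± 0.07 (adjusted p = 0.00873), and the unnamed X-linked AK079313 by 0.55 ± 0.07 (adjusted p = 0.000791). Tsix, the antisense partner of Xist, was at least 4.27-fold lower in males, where it was not well above background on any array (adjusted p = 5.74e-14). AK076900, on chromosome 15, fell by 0.38 ± 0.06 log2 (adjusted p = 0.0258). AK053080, AK079313 and AK076900 fall outside the rule for named genes and were named after their values were seen. Uty was not well above background on any array by any of its 3 probes and was not tested. Kdm5c and Kdm6a, X-linked histone demethylases, had -0.26 ± 0.05 and -0.46 ± 0.09 log2 and did not pass over all genes. Adjusted over the list alone, 5 of 5 X-linked genes escaping inactivation passed, with a list mean of -1.79 ± 0.04 log2 (camera adjusted p = 7.85e-27; adjusted p = 4.54e-06 with an estimated correlation). This X-linked list includes Xist at -7.57 log2, which carries most of its mean. Eif2s3x, Kdm6a and Kdm5c lay between -0.46 and -0.26 log2. Of the 7 Y-linked genes 4 were measured, too few for a list test, and 3 passed when adjusted over the list alone. Zfy1 had 0.05 ± 0.05 log2.

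Erythroid markers were higher in males, with all 28 measured genes above 0 and a list mean of 0.23 ± 0.07 log2 (camera adjusted p = 3.48e-19; adjusted p = 0.159 with an estimated correlation). Trim10 had 0.27 ± 0.09, Nfe2 0.26 ± 0.08, Ank1, the ankyrin of red cells, 0.24 ± 0.08 and Ermap 0.27 ± 0.10 log2, none past the threshold. Sts had 0.37 ± 0.08, Retnlg 0.47 ± 0.11, Phyhip 0.35 ± 0.09, Trim56 0.31 ± 0.07, Cd99 0.19 ± 0.04, Jarid1c -0.32 ± 0.07, Ccl4 -0.37 ± 0.08 and Ifna9 -0.25 ± 0.05 log2, also not past over all genes. Adjusted over the list alone, Ccl4 (inflammatory), Retnlg and Mmp8 (granulocyte) and Fabp4 (adipocyte) passed. Camera further called hepatocyte markers (0.25 ± 0.17), megakaryocyte markers (0.12 ± 0.07) and inflammatory cytokines and NF-kB targets (-0.08 ± 0.04 log2), with adjusted p = 2.9e-07, 1.37e-05 and 0.00161, and 0.531, 0.475 and 0.233 with an estimated correlation. Granulocyte markers had 0.16 ± 0.09, and 0.11 without female control replicate 25, and pancreas markers 0.60 ± 0.35, and 0.32 without male control replicate 31 (camera adjusted p = 2.21e-07 and 2.39e-09; both 0.475 with an estimated correlation). Cell proliferation had 0.10 ± 0.09 log2, and the call ended at 0.04 without male control replicate 41, while without female control replicate 35 or female UV-Titan replicate 8 the list was 0.06, still called. Glucose and amino acid metabolism had 0.10 ± 0.10, and the call ended at 0.055 to 0.089 without female control replicate 25, female UV-Titan replicate 16, male control replicate 33 or male UV-Titan replicates 3 or 5, while without male UV-Titan replicate 17 it was 0.17. Immediate early genes had -0.06 ± 0.04, and the call ended at -0.06 to -0.04 without male control replicates 41 or 33, female control replicates 35 or 25, female UV-Titan replicate 8 or male UV-Titan replicate 3. Bile acid synthesis had 0.08 ± 0.07, and the call ended in 8 omissions, farthest away at 0.018 without female control replicate 25. Cholesterol synthesis had 0.06 ± 0.09, and the call ended in 8 omissions, farthest away at -0.0035 without male control replicate 43. In the liver channel alone the hepatocyte, glucose and bile acid lists had small values of the opposite sign. Camera called 12 of 36 lists between the sexes, fry called 1, and camera with an estimated correlation called 1, the X-linked genes. Adult liver genes higher in males and those higher in females were not called, at -0.02 ± 0.06 and -0.01 ± 0.07 log2 (adjusted p = 0.612 and 0.912).

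Lists for the damage and stress responses that the exposure could touch were not called in females with all arrays and the processing chosen, and 4 of them were called in other settings. Retinoid signalling and metabolism, a list included because a published study of these animals is known to discuss it and so not independent evidence, had a mean of 0.11 ± 0.05 log2 in females (camera adjusted p = 0.408; 0.06 log2 without female control replicate 25), -0.0065 ± 0.0467 in males (adjusted p = 0.605) and 0.05 ± 0.03 over both (adjusted p = 0.703), with 0 of 32 genes past in any of these when adjusted over the list alone. In females Cyp26b1, which degrades retinoic acid, had 0.92 ± 0.25, Rarb, a retinoic acid receptor, 0.26 ± 0.11 and Adh7 -0.22 ± 0.09 log2. In males Adh4 had 0.30 ± 0.14, Rdh16 0.27 ± 0.12, Rxrg 0.26 ± 0.12 (-0.05 in the liver channel alone) and Cyp26a1 -0.17 ± 0.06 log2, and in females Cyp26a1 had -0.06 ± 0.07. None passed. In females p53 targets and DNA damage response had 0.04 ± 0.03, DNA repair -0.01 ± 0.05, oxidative stress and NRF2 targets 0.04 ± 0.05, heat shock and unfolded protein response -0.0033 ± 0.0495, inflammatory cytokines and NF-kB targets 0.0061 ± 0.0508, interferon response 0.0021 ± 0.1460, immediate early genes 0.10 ± 0.06 and metal handling 0.09 ± 0.05 log2, with camera's adjusted p from 0.154 to 0.908. Camera called immediate early genes in 7 of 36 other settings, at 0.11 to 0.18 log2 (smallest adjusted p = 0.00275, in the liver channel alone), and in none that left out 1 array. It called DNA repair in 3, at -0.02 with every probe as its own unit, -0.04 with array weights and -0.07 without female control replicate 35 (adjusted p = 0.0314, 0.0124 and 0.00043). It called heat shock and unfolded protein response at -0.04 without female UV-Titan replicate 16 and interferon response at -0.07 without female UV-Titan replicate 21 (adjusted p = 0.0459 and 0.0147). Mt1 and Mt2, the metallothioneins, had 0.03 ± 0.15 and -0.11 ± 0.15 log2, and Cdkn1a, the p53 target p21, 0.02 ± 0.15 log2. In males Mt1, Mt2 and Cdkn1a had -0.06 ± 0.15, -0.09 ± 0.14 and -0.02 ± 0.14, Saa1 and Saa2 0.16 ± 0.12 and 0.19 ± 0.09, and Alb and Afp -0.27 ± 0.33 and -0.58 ± 0.42 log2, none past. With 1 array left out Afp in males lay between -0.83 (without male UV-Titan replicate 5) and -0.09 log2 (without male UV-Titan replicate 17).

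Of the lists for other functions and cell types, camera did not call these in females with all arrays and the processing chosen. The list means were 0.11 ± 0.06 for the growth hormone and IGF axis, 0.14 ± 0.08 for adult liver genes higher in males, 0.10 ± 0.08 for lymphocyte markers, 0.04 ± 0.16 for stellate cell and matrix genes, 0.11 ± 0.10 for adipocyte markers, 0.05 ± 0.14 for bile duct cell markers, 0.07 ± 0.50 for pancreas markers, 0.08 ± 0.41 for muscle markers, -0.0040 ± 0.0729 for the respiratory chain, 0.06 ± 0.08 for fatty acid and triglyceride synthesis, 0.05 ± 0.08 for the circadian clock and 0.02 ± 0.06 log2 for X-linked genes escaping inactivation. Camera's adjusted p for them lay between 0.109 and 0.913. With 1 array left out camera called lymphocyte markers at 0.23 without female control replicate 40, adult liver genes higher in males at 0.23 without female control replicate 35, the respiratory chain at -0.10 without female control replicate 25, and stellate cell and matrix genes at -0.04 log2 without female UV-Titan replicate 16 (adjusted p = 0.000272, 0.0293, 0.00361 and 0.0421). In other settings it called adult liver genes higher in males in 3 settings (0.14 to 0.20), the growth hormone and IGF axis in 2 (0.10 and 0.11), adipocyte markers in 1 (0.16), pancreas markers in 1 (-0.15), the respiratory chain in 2 (-0.07 in the liver channel alone and -0.09 without slide 5) and stellate cell and matrix genes in 2 (-0.01 with every probe as its own unit and -0.09 log2 without slide 5).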

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

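All tests of explanations in this part, and the counts of other splits of the arrays, were written after the results were seen. In groups of 4 or 5 arrays, 4 of 111 list scores and 25 of 384 log2 ratios of named genes had an array far from the others of its group by Dixon's criterion, where chance flags about 1 in 20 groups.

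The first pattern was the higher megakaryocyte and platelet list in female UV-Titan livers. A difference in the reference channel is argued against by the liver channel alone, centred on each array's median, where the list rose by 0.504 ± 0.106 log2 while the reference moved by 0.0352 ± 0.0425. A difference between slides is argued against by 0.487 ± 0.0818 log2 with slide as a block. The list minus the erythroid list gave 0.351 ± 0.155, and minus the lymphocyte list 0.431 ± 0.103. These values argue against a rise of every blood cell list by the same log2 amount. More blood cells of every kind stays open, because the test takes extra blood to move every list equally. The list minus the granulocyte list gave 0.0806 ± 0.0751, so a joint rise of platelet and granulocyte transcripts stays open, as do age, litter and the exposure itself, which the labels do not separate. In the liver channel alone, here quantile-normalised between arrays, Afp differed by -0.000543 ± 0.0625 and the fetal and imprinted list by 0.0398 ± 0.0501 log2. These are small values for genes that fall with age. By ratio both were higher, the list by 0.216 log2 and called by camera. No array of known age gives the size to expect, so age was not tested.

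The second pattern was the hepatocyte list, higher by ratio in female UV-Titan livers. With each array centred on its median, the list fell by 0.417 ± 0.233 log2 in the reference channel and moved by 0.185 ± 0.102 in the liver channel, so a difference in the reference channel may account for most of the ratio. A difference between slides as the whole cause is argued against by 0.396 ± 0.101 log2 with slide as a block. The 3 arrays of slide 5 had the highest list scores in the reference channel, 0.383 to 0.694, close above the -0.358 to 0.366 of the other 13. Without slide 5 the ratio was 0.582 ± 0.166, so that slide alone does not make the change. A biological difference stays open and was not tested apart from the reference.

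The third pattern was pancreas and muscle transcripts on 3 male arrays. On both male control replicates 31 and 33, 15 of 17 pancreas genes were brighter in the liver channel than on each of the other 14 arrays, and on male UV-Titan replicate 5, 10 of 12 muscle genes were brighter than on each of the other 15. A difference in the reference channel is argued against because the lists were higher there, by 0.319 (pancreas) and 0.201 log2 (muscle), where it needed lower values. The SD of the scores on the other arrays was 0.106 for pancreas and 0.0994 for muscle. Pieces of neighbouring tissue taken with the liver may be the source, as a hypothesis. No biological explanation was tested.

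Male UV-Titan replicate 5 lay above the other 3 arrays of its group in the muscle list, at 1.88, and in the log2 ratios of Tnni2 (1.73), Tnnt3 (1.16), Myl1 (1.68), Myh8 (3.48), Atp5o (0.724) and Cd99 (-0.507). Male UV-Titan replicate 17 lay below its group in the granulocyte list (-0.229), the megakaryocyte list (-0.117), Treml1 (3.39) and Gp5 (2.37), and above it in Mzb1 (-1.95). Male UV-Titan replicate 4 lay below its group in Mt1 (1.48) and Mt2 (1.79), and replicate 3 in Cth (2.67). Male control replicate 33 lay below its group in the list of X-linked genes escaping inactivation (-1.02), Tjp3 (-0.242) and Mmp9 (-0.696), and replicate 31 above it in Itih4 (3.24). Female UV-Titan replicate 8 lay above its group in Vwf (3.71) and Ehhadh (4.60), and replicate 21 in Sh3bp4 (-1.48). Female UV-Titan replicate 16 lay below its group in Myc (-1.60), Ly6c (-0.726) and Ermap (4.12). Female UV-Titan replicate 10 lay above its group in Phyhip (1.58), Adh4 (2.60) and Gp6 (1.98), and below it in Mmp8 (3.11).

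Camera called 20 lists in the test of whether the exposure effect differed between the sexes (female minus male), and 0 with an estimated correlation (adjusted p from 0.3 to 0.562). The 10 called in every omission of an array were hepatocyte markers 0.744, glucose and amino acid metabolism 0.436, granulocyte markers 0.387, fatty acid oxidation 0.387, megakaryocyte markers 0.358, acute phase proteins 0.349, xenobiotic metabolism 0.337, bile acid synthesis 0.261 (0.134 without female control replicate 25), macrophage markers 0.154 and pancreas markers 1.11 log2 (0.571 without male control replicate 31, and -0.00858 without replicates 31 and 33). In the liver channel alone 5 of the 20 were called (fatty acid oxidation 0.195, granulocyte 0.161, megakaryocyte 0.286, pancreas 1.24 and cell proliferation -0.227), and hepatocyte markers were 0.0303. The 10 apart from those called in every omission lost the call without at least 1 array, and their lowest and highest values with 1 array left out follow each. They were fetal and imprinted genes 0.251 (0.149 without male UV-Titan replicate 17, 0.336 without male UV-Titan replicate 5), adult liver genes higher in females 0.2 (0.0786 without female control replicate 25, 0.34 without replicate 35), cholesterol synthesis 0.149 (0.0223 without male control replicate 43, 0.24 without replicate 41), endothelial markers 0.148 (0.0647 without female control replicate 25, 0.201 without male UV-Titan replicate 5) and oxidative stress 0.109 (0.0684 without female control replicate 25, 0.178 without replicate 35). They were further the respiratory chain 0.0852 (-0.00676 without female control replicate 25, 0.18 without replicate 35), DNA repair -0.0629 (-0.113 without female control replicate 35, -0.0366 without replicate 40), stellate cell and matrix genes -0.122 (-0.214 without male UV-Titan replicate 17, -0.0216 without replicate 5), cell proliferation -0.144 (-0.253 without male control replicate 41, -0.0721 without replicate 43) and muscle markers -0.483 (-0.694 without male UV-Titan replicate 3, 0.0367 without replicate 5).

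Other splits of the same arrays into groups of the same sizes could not test the counts of called genes for the exposure, because limma's real count was 0 and every split gives at least as many. The highest other split called 0 genes for females, 8 for males, 7 over both sexes and 2 for the difference between the sexes. By genes below an unadjusted p of 0.05, among genes with a value on every array, 12 of 56 splits gave as many for females (real 1294, highest other 2568), 14 of 35 for males (956 and 2566), 17 of 100 drawn over both sexes (1364 and 2825) and 50 of 100 drawn for the difference (822 and 2319), so chance is not excluded for any of these counts. The splits were made without regard to slide, so they do not test the exposure within slides. As many called lists came in 9 of 56 splits for females (real 15, highest other 19), 22 of 35 for males (11 and 20), 42 of 100 over both sexes (11 and 22), 5 of 100 for the difference (20 and 21) and 41 of 100 between the sexes (12 and 22), so chance is not excluded for the number of called lists in any comparison. For genes between the sexes, 3 of 100 drawn splits gave at least as many as the real split (9), the real split among them. The others called 37 and 331 genes, so the count alone does not exclude chance. All of the 9 genes but AK076900 lie on X or Y sequence. The split with 331 genes was the highest of the 100, and what set its groups apart was not tested.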

How the results depend on the processing

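The fits without tissue arrays or slide 5, and the liver channel with slide as a block, were chosen after seeing the data. No paired analysis was possible by replicate number, because the groups compared share none; slides that held both groups paired them instead, as a block and within slides. The list test could not take slide as a random block. Signal over background limited the genes tested. Median centring left the median of all genes at 0.27 log2 in females, 0.37 in the difference between the sexes and 0.13 between the sexes, and its values are relative to that. For single genes and lists, 4712 values counted as kept under other settings, 233 lost and 58 gained a call and 62 reversed. With 1 array left out the counts were 4019, 113, 17 and 11. Values counted as kept include sign changes of at most 1 SE where neither setting called the value. The counts of reversals therefore leave out these small sign changes. The cause was not tested for any change below unless stated. Called genes in females were 1 with slide as a fixed block, 1 with scan day, 6 with array weights, 6 at an adjusted p below 0.10 and 49 at an unadjusted p below 0.05 with 1.5-fold (0 to 1 with an array left out). In males they were 1 with the scanner's processed signals and 36 with 1.5-fold (0 to 0). Over both sexes they were 1 without background correction, 1 with slide fixed, 11 with slide random, 10 with scan day, 9 with array weights, 10 at 0.10 and 5 with 1.5-fold (0 to 11, with 11 without male control replicate 43, 3 without female control replicate 35, 1 without female UV-Titan replicate 21 and 1 without replicate 16). The difference between the sexes had 144 with 1.5-fold (0 to 0). Between the sexes 3 were called where all arrays had to be well above background, a filter that leaves out genes dim in 1 sex (8 to 9). Called lists in females were 7 in the liver channel alone, 1 with an estimated correlation and 3 in the liver channel with slide (12 to 17). In males they were 0 with an estimated correlation and 7 without the pancreas arrays (9 to 15), over both sexes 0 with an estimated correlation (9 to 18, with 18 without male UV-Titan replicate 17), and in the difference 6 in the liver channel, 0 with an estimated correlation, 12 without slide 5 and 5 in the liver channel with slide (14 to 21). Between the sexes 1 was called with an estimated correlation (9 to 17). The megakaryocyte list lost its call with an estimated correlation in males (0.174), over both sexes (0.353), in the difference (0.358) and between the sexes (0.121).

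In females these reversed in the liver channel alone and with slide: fatty acid oxidation -0.0269 and -0.0286, growth hormone axis -0.0135 and -0.0304, lymphocyte -0.00814 and -0.0233 (array weights -0.0408), metal handling -0.0559 and -0.0357, adult liver genes higher in females -0.0101 and -0.0243, Ttr -0.0821 and -0.0916, Tspan33 -0.211 and -0.102, Afp -0.000543 and -0.00927, Alb -0.0682 and -0.0625, and Cyp26a1 0.0108 and 0.0116. Erythroid markers reversed in the liver channel (-0.0181), adult liver genes higher in males with slide (-0.000833), bile duct -0.0949 and stellate -0.0859 without slide 5, stellate -0.0144 with every probe, and Mt1 -0.149 with array weights. Median centring gave pancreas -0.151, proliferation 0.0116, heat shock 0.0915 and respiratory chain 0.11. In males the liver channel gave hepatocyte 0.0135, Etfa 0.0124 and Rxrg -0.0482, omitting slide 5 gave hepatocyte 0.0497, glucose 0.00243 and Alb 0.103, processed signals gave Rdh16 -0.0878, and omitting the pancreas arrays gave pancreas 0.0764 and Clps 0.0298, by construction. Over both sexes pancreas was 0.0721 without those arrays, Alb -0.0285 and -0.0328 in the liver channel and with slide, and centring gave respiratory chain 0.0615, Mt1 0.0926 and Mt2 0.0109. In the difference, centring gave DNA repair 0.00974, stellate 0.0135, proliferation 0.00734 and Ptpru -0.00772, the liver channel gave respiratory chain -0.02 and adult liver genes higher in females -0.0246 (-0.0136 with slide, endothelial -0.0581), and omissions gave respiratory chain -0.0174 (slide 5), pancreas -0.00858 and muscle 0.0367. Between the sexes bile acid synthesis was -0.0377 and -0.038, glucose -0.00688 and hepatocyte -0.00713 in the liver channel, and Zfy1 -0.0607 with centring. With an array left out, values ranged in females from -0.0684 to 0.0836 (interferon), -0.0425 to 0.0995 (stellate), -0.0959 to 0.0908 (respiratory chain) and -0.0988 to 0.0179 (Cyp26a1), in males from -0.214 to 0.00243 (glucose), -0.342 to 0.0497 (hepatocyte) and -0.537 to 0.103 (Alb), over both from -0.0926 to 0.000791 (respiratory chain), in the difference from -0.694 to 0.0367 (muscle) and -0.00676 to 0.18 (respiratory chain), and between the sexes from -0.00349 to 0.105 (cholesterol). Over the arrays left out the megakaryocyte list stayed called, at 0.47 to 0.571 in females, 0.125 to 0.251 in males, 0.322 to 0.392 over both, 0.281 to 0.407 in the difference and 0.0899 to 0.159 between the sexes.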
